A study of Mus musculus with 6 samples.

How the data were processed

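Bulk RNA sequencing of whole left gastrocnemius, a calf muscle, was analysed in 6 male C57BL/6J mice aged 12 weeks. Per the labels' protocols, 3 mice were normal controls and 3 had lost a 2 mm piece of the left sciatic nerve, with the muscle taken 2 weeks later. The same protocols state that total RNA was extracted with Qiazol and that libraries followed a standard Illumina mRNA protocol with paired-end reads of 50 bp. Replicates are separate mice. Bowtie2 2.2.9, RSEM 1.3.0, edgeR 3.12.1 and the genome build NCBIM37 are named in the submitters' processing notes, which give no role or order for them. Strandedness, filters and the annotation release are not given in the sources used here.

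The table deposited by the authors holds 22187 gene rows, each with an Ensembl identifier, a symbol, a biotype and 6 columns of expression signal. Its unit was read from the values, since no header names one. Below 100, 100% of the values above 0 in each column lay within 0.00055 of a whole multiple of a single step, which is 0.01 times the factor of that library. Divided by these factors the column totals were 999951 to 999983, as TPM rounded to 0.01 would give. The search for each step began from the column total under that reading, so these totals are no separate support for it. The deposited signal was therefore treated as TPM (relative transcript abundance corrected for gene length) multiplied by 1 factor per library. These factors lay between 0.977 and 1.13, with a mean of 1.09 in controls and 1.02 in denervated muscle. What produced the factors is not given in the sources used here. For RNAs shorter than a sequenced fragment TPM depends strongly on the effective length used, which is not given in the sources used here, so levels of small RNAs and all shares of the total are uncertain. TPM keeps no record of the number of reads, so the depth of each library is unknown, and no interval or floor from counting was computed. An exact 0 in such a table can be a failed estimate, and a gene at 0 in a whole group is described only as listed at 0.

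Values were used as deposited, on the scale log2(level + 1). This pseudocount of 1 understates the change of low genes. Genes at 0.5 or more in at least 3 of the 6 libraries were tested, which left 12392. Denervated and control muscle were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 4 residual degrees of freedom). The test was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A test of counts was planned for the case that the table held counts. The values are not counts, so the test planned for normalized values was used. An exact permutation test of a single gene with 3 mice against 3 cannot give a two-sided p below 0.1.

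Before the data were examined, 21 gene lists and 13 lists of cell type markers were fixed. Lists with 3 or more tested members entered camera from limma, with a preset correlation between genes of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. No lymphocyte marker passed the level filter, so 33 lists were tested. The number of members past the threshold is given over all genes tested, and where it differs also as adjusted over the list alone.

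Genes were named by a rule fixed at the same time. It took 12 index genes, the 10 largest rises and the 10 largest falls among genes past the threshold without overlap between groups and above the median level, up to 3 members in each direction per list, and the 5 most abundant genes. A list with no called member would have given its 2 most abundant members. Any other gene is said to have been chosen after its values were seen. Some genes that the rule takes are not reported here.

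Gene symbols are those of the table. A GENCODE M21 annotation on GRCm38 matched 20547 of the 22187 identifiers and was used only for current symbols and gene lengths. It is not the build named by the submitters, so no coordinates are given. Of the tested rows, 32 were identical in all 6 libraries to another row, so their reads cannot be assigned to 1 gene. The same uncertainty holds for near-identical copies, such as ribosomal protein genes with many pseudogenes, the globin genes, Amd1 and its copy, and the small RNA families. Without a stated strand, reads of antisense genes cannot be separated from those of their partners.

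The alternatives were a replicate block, leaving out each library, median-ratio and quantile scaling, totals without the 20 most abundant genes, no filter or a mean level of 1 or more, pseudocounts of 0.1 and 0.01, limma without trend or with robust variances, and a minimum log2 fold change of 1. Added after seeing the data were TPM without the library factor, 1 row per set of identical rows, leaving out control 1 and denervated 2 together, and equal protein-coding totals. The table holds no fold changes or p-values of the authors, so that comparison was not run. The procedure was tested on simulated data for the same 12392 genes with 3 libraries per group. It recovered 40% of 50 genes changed by a log2 size of 0.5, 94% of 50 changed by 1 and 100% of 50 changed by 2. Of the unchanged genes 15 were called. Only these genes and 50 changed by 3 were moved, a far smaller share than the 47.3% called in the data. With so few changes the adjustment demands a smaller unadjusted p, so these shares do not measure the recovery in the data.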

Results

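Transcript levels were compared in whole gastrocnemius of 3 control mice and 3 mice whose sciatic nerve had been cut 2 weeks earlier. The data used here hold no measure of atrophy, such as muscle mass or fibre size. Levels are TPM multiplied by a library factor and are given as mean ± SD over 3 mice per group. Fold changes are denervated minus control on the log2(level + 1) scale, with their standard error (SE) where shown. The depth of the libraries is unknown. Between 17875 and 20243 of 22187 rows were above 0, with 18049 ± 165 rows in controls and 19681 ± 625 in denervated muscle. Spearman correlations across genes were 0.957 to 0.976 within groups and 0.848 to 0.863 between groups, and the first principal component held 76.7% of the variance.

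Close to every second tested gene differed between denervated and control muscle with values as deposited. The controls are described as normal mice, so effects of the operation cannot be told apart from those of the lost nerve. Of 12392 genes, 2840 were higher and 3017 lower in denervated muscle at an adjusted p below 0.05, or 47.3% of those tested, with 6775 at an unadjusted p below 0.05. The log2 fold change reached 1 or more in size for 758 of the higher and 673 of the lower genes. The 3 values of each group lay apart without overlap for 5813 of the 5857 called genes and for 57.5% of all tested genes, against 10% by chance. The number of called genes and the balance of rises and falls depend on the scaling. With totals that left out the 20 most abundant genes, 4966 genes were higher and 1614 lower, or 75.5% of calls higher against 48.5% as deposited, and the median of all genes moved from -0.01 to 0.23. With equal protein-coding totals 9038 were higher and 668 lower (93.1% higher), and the median moved to 0.60.

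That spread between scalings goes with a shift in RNA classes. Protein-coding transcripts made up 31.7% ± 0.977 of the TPM total in controls and 18.1% ± 0.770 in denervated muscle. Transcripts of the mitochondrial genome fell from 11.7% ± 0.610 to 2.83% ± 0.273, and the remaining protein-coding genes lay at 19.7% to 20.5% in controls and at 14.7% to 16.2% in denervated muscle. Small nuclear RNAs, the RNA of splicing complexes, went from 5.41% ± 0.420 to 11.6% ± 0.989, and small nucleolar RNAs, guides of RNA modification, from 2.2% ± 0.545 to 6.60% ± 0.325. The 3 libraries of each group did not overlap for any of these shares. The most abundant rows were AC099934.1 and AC157822.1, a pair of non-coding genes with identical values, which held 55.2% ± 2.40 and 55.4% ± 2.08 of the total. Their log2 fold change was -0.081 (adjusted p = 0.746). How TPM was corrected for the length of such short RNAs is not given in the sources used here, so their levels, and every share of the total, depend on a correction that could not be checked.

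**Figure D1:**
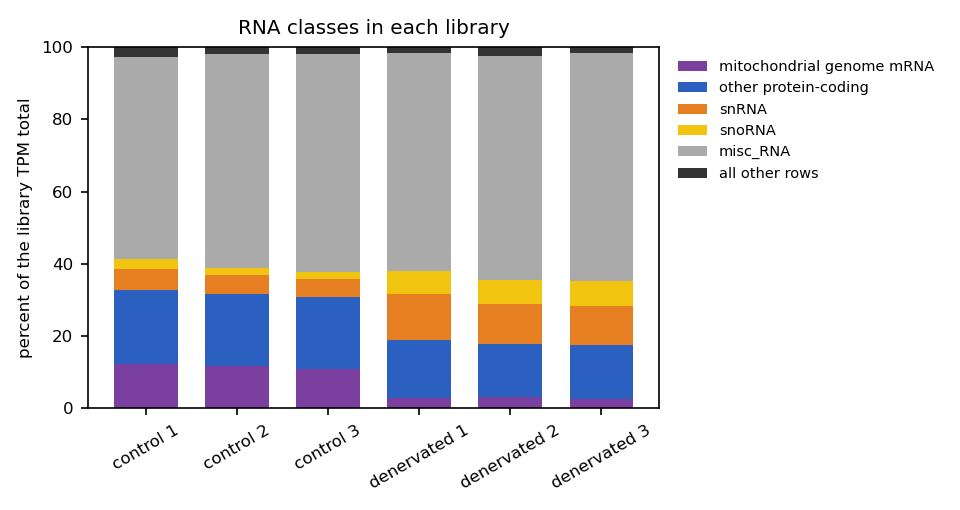
Share of each RNA class in the TPM total (percent, vertical axis) for the 3 control and 3 denervated libraries (horizontal axis), 1 stacked bar per library. Mitochondrial genome mRNA shrank from 11.7% to 2.83% on average, while snRNA grew from 5.41% to 11.6% and snoRNA from 2.2% to 6.60%.

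More genes of the neuromuscular contact rose than fell. Chrna1 and Chrnd, subunits of the muscle acetylcholine receptor, rose from 1.66 ± 0.195 to 106 ± 6.90 and from 0.537 ± 0.153 to 57.5 ± 3.91. Chrng, the subunit of the fetal receptor, rose from 0.133 ± 0.184 to 35.1 ± 2.46. Ncam1, a cell adhesion molecule, rose from 2.52 ± 0.809 to 51.8 ± 5.89. Ache, which breaks down acetylcholine, fell from 9.32 ± 0.407 to 1.61 ± 0.386, and the adult sodium channel gene Scn4a had a log2 fold change of -0.85 as deposited, which turned positive (0.027) with equal protein-coding totals. Of 20 tested members of the receptor and junction list, 11 were higher, 2 lower and 7 not called. The log2 fold changes were 5.33 (SE 0.094, adjusted p = 2.35e-07) for Chrna1 and -1.99 (SE 0.124, adjusted p = 1.46e-05) for Ache, with no overlap between the 3 mice of each group. Camera gave the list an adjusted p of 7.11e-05, and the adjusted p was 0.218 with an estimated correlation.

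More myogenic regulators were higher than lower. Myog, a transcription factor of muscle differentiation, rose from 2.48 ± 0.489 to 109 ± 9.45. Runx1, a transcription factor, rose from 0.330 ± 0.155 to 34.0 ± 1.99, and Gadd45a, a stress-response gene, from 4.16 ± 0.384 to 253 ± 32.1. The nuclear receptor gene Nr4a1 fell from 54.4 ± 14.2 to 5.97 ± 2.05, and Atf4 and Hdac9 had log2 fold changes of -0.78 and -0.57. Of 21 tested members 15 were higher and 5 lower, or 6 lower when adjusted over the list alone. Camera gave an adjusted p of 0.00022, and 0.264 was the adjusted p with an estimated correlation.

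**Figure D2:**
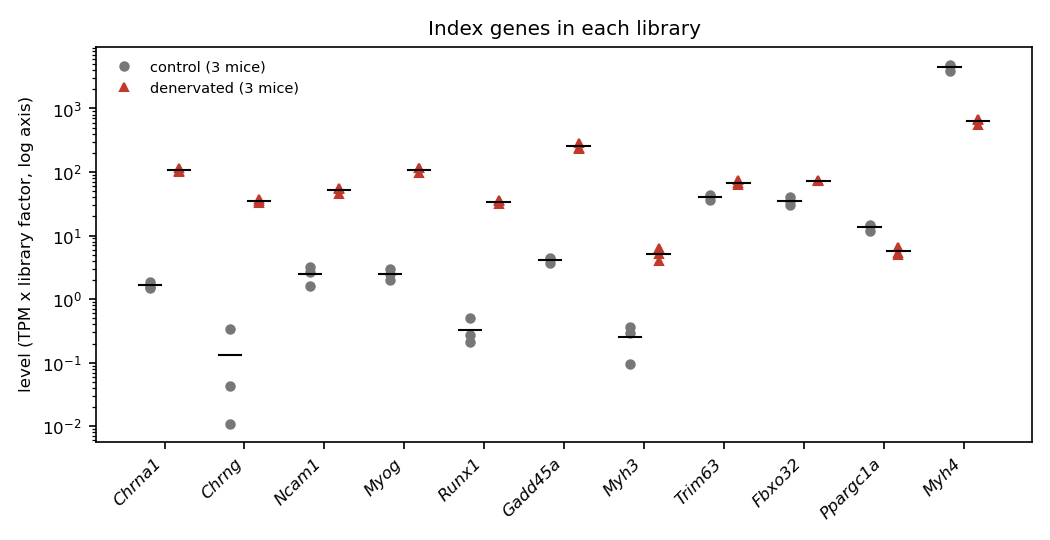
Level of index genes (TPM times library factor, log axis) in 3 control mice (grey circles) and 3 denervated mice (red triangles), with group means as bars. Chrna1 went from a mean of 1.66 to 106 and Gadd45a from 4.16 to 253, whereas Myh4 went from 4485 to 638.

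Most contractile genes of fast fibres were lower. Myh4, the myosin heavy chain of the fastest fibres, fell from 4485 ± 503 to 638 ± 73.1 (log2 fold change -2.81, SE 0.133, adjusted p = 4.37e-06). Mybpc2, the fast form of myosin-binding protein C, fell from 531 ± 57.2 to 56.0 ± 12.4, and Casq1, which stores calcium in the sarcoplasmic reticulum, from 920 ± 4.66 to 215 ± 41.4. Myh2, the myosin of fast oxidative fibres, was the only higher member of its list, at 175 ± 26.6 and 281 ± 40.5. Of 20 genes of fast fibres 17 were lower and 1 higher (camera adjusted p = 1.05e-07, and adjusted p = 0.218 with an estimated correlation). Their median depended on the scaling, at -1.18 as deposited, -0.49 with quantile normalization and -0.28 with equal protein-coding totals.

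Slow-fibre genes went both ways. Sln, an inhibitor of the calcium pump, rose from 1.89 ± 1.29 to 240 ± 36.2, and the slow troponin genes Tnnt1 and Tnni1 rose from 1.02 ± 0.409 to 40.2 ± 6.47 and from 0.741 ± 0.0974 to 14.6 ± 1.67. Mybpc1 and Casq2 had log2 fold changes of -0.65 and -0.71. The 14 members held 5 higher and 2 lower, and the list test did not pass (adjusted p = 0.134).

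Developmental and fibre-remodelling genes were mostly higher. Myh3, the embryonic myosin heavy chain, rose from 0.251 ± 0.137 to 5.09 ± 1.18. Ankrd1, an ankyrin repeat protein of stretched and injured muscle, rose from 1.07 ± 0.255 to 97.1 ± 18. The muscle fusion genes rose too. Mymx, listed as Gm7325 (ENSMUSG00000079471), went from 0.277 ± 0.342 to 47.4 ± 9.28, and Mymk, listed as Tmem8c (ENSMUSG00000009214), from 0.120 ± 0.0384 to 10.5 ± 1.25. Actc1, the cardiac actin gene, fell from 7.79 ± 1.81 to 0.768 ± 0.158. Of 16 members 13 were higher, or 14 adjusted over the list alone, and 1 lower (camera adjusted p = 2.01e-06, and adjusted p = 0.218 with an estimated correlation).

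Most genes of energy metabolism were lower in each of 5 lists. All 24 tested genes of glycolysis and glycogen but 1 were lower, with a median log2 fold change of -1.89. Eno3, the muscle enolase, fell from 1331 ± 82.2 to 188 ± 29.0, Pfkfb1, a regulator of glycolysis, from 20.9 ± 1.85 to 2.09 ± 0.179, and Fbp2, the muscle fructose bisphosphatase, from 21.1 ± 5.95 to 2.08 ± 0.106. Slc16a3, an exporter of lactate, fell from 84.6 ± 6.92 to 7.34 ± 1.78. All 20 genes of the tricarboxylic acid cycle were lower (median -1.15), among them Idh3a at 97.6 ± 1.73 and 27.9 ± 0.753. Genes of fatty acid uptake and oxidation had 26 of 30 lower, or 27 adjusted over the list alone (median -0.93). Perm1, a regulator of muscle energy genes listed as 2310042D19Rik (ENSMUSG00000078486), fell from 55.9 ± 4.20 to 5.28 ± 0.384, and Ppargc1a, a coactivator that drives mitochondrial biogenesis, from 13.7 ± 1.49 to 5.64 ± 0.912.

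Of 52 nuclear genes of the respiratory chain and ATP synthase 49 were lower, or 51 adjusted over the list alone (median -1.04). Cox7a1, a muscle subunit of cytochrome oxidase, fell from 358 ± 32.0 to 103 ± 13. All 13 mRNAs of the mitochondrial genome were lower (median -2.2), with mt-Co3 at 30050 ± 379 in controls and 7812 ± 460 after denervation. The camera adjusted p was 2.25e-14 for glycolysis, 5.29e-11 for the tricarboxylic acid cycle, 5.09e-10 for fatty acids, 3.37e-18 for the nuclear respiratory genes and 2.71e-09 for the mitochondrial genome. Each of these 5 lists had an adjusted p of 0.218 with an estimated correlation. Their medians stayed below 0 under all 5 other scalings, although equal protein-coding totals brought them to -1.05 for glycolysis, -0.26 for the tricarboxylic acid cycle, -0.07 for fatty acids, -0.16 for the nuclear respiratory genes and -1.30 for the mitochondrial genome. Those totals moved the median of all genes to 0.60. Taken less that median, the 5 lists stood at -1.65, -0.86, -0.67, -0.77 and -1.90 in the same order.

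Polyamine and creatine genes held some of the steepest falls in the table. Amd1, which makes the aminopropyl donor of polyamine synthesis, fell from 111 ± 17.9 to 6.44 ± 0.767, with reads that a near-identical copy can share. Smox, spermine oxidase, fell from 101 ± 26.8 to 6.84 ± 0.444, and Ckmt2, a mitochondrial creatine kinase, from 651 ± 69.1 to 114 ± 8.67. Ampd3, an AMP deaminase, rose from 1.87 ± 0.137 to 29.1 ± 2.30. Odc1 and Azin1, ornithine decarboxylase and its antizyme inhibitor, had log2 fold changes of 0.59 and 0.65. The call of Odc1 was lost without denervated 1 (adjusted p = 0.0507), and that of Azin1 without control 2, denervated 1 or denervated 3 (adjusted p = 0.0519, 0.0717 and 0.0639). The list held 5 higher and 7 lower of 16 and did not pass its test (adjusted p = 0.223). Its median of -0.17 turned positive under totals without the 20 most abundant genes and under equal protein-coding totals.

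Transcripts of protein breakdown genes changed unevenly. Trim63 and Fbxo32, the muscle ubiquitin ligases MuRF1 and atrogin-1, rose from 40.2 ± 3.98 to 68.3 ± 5.37 and from 35.1 ± 5.19 to 73.2 ± 1.64 (log2 fold changes 0.75 and 1.05, adjusted p = 0.000789 and 0.000217, no overlap between mice). Mdm2, a ligase for p53, rose from 8.89 ± 0.569 to 28.4 ± 3.56, whereas Asb2 fell from 92.9 ± 5.85 to 41.2 ± 5.99. Of 21 ligases 5 were higher and 6 lower (adjusted p = 0.559), and the median of -0.14 turned positive under totals without the 20 most abundant genes and under equal protein-coding totals. Among 31 subunits of the proteasome 18 were higher and 0 lower. Psmd11 rose from 12.2 ± 1.71 to 25 ± 4.15 and Psmd4 from 49.9 ± 2.92 to 89.9 ± 6.28. Camera gave the proteasome an adjusted p of 0.000351, and the adjusted p was 0.383 with an estimated correlation.

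In autophagy and lysosome genes 10 of 28 were higher and 3 lower, or 15 and 3 adjusted over the list alone. Map1lc3a, an autophagosome protein, rose from 68.9 ± 6.80 to 303 ± 45.9. Tfeb, a regulator of lysosome genes, had a log2 fold change of -0.81. Lamp1 and Bnip3 were called lower at -0.25 and -0.44, and their calls did not withstand the loss of single libraries. Bnip3 missed the threshold without control 1, control 3, denervated 2 or denervated 3 (adjusted p = 0.0575, 0.082, 0.0702 and 0.0746), and Lamp1 without control 1, control 2, control 3, denervated 2 or denervated 3 (adjusted p = 0.0633, 0.075, 0.0889, 0.0627 and 0.0581). With totals that left out the 20 most abundant genes Lamp1 stood at 0.093 and Bnip3 at -0.094 (limma adjusted p = 0.351 and 0.537). The list had a camera adjusted p of 0.0207, and 0.354 was the adjusted p with an estimated correlation. Growth and FoxO signalling genes went both ways, with 12 of 29 higher, or 13 adjusted over the list alone, and 9 lower (adjusted p = 0.21). Fst, which binds myostatin and activins, rose from 0.372 ± 0.111 to 12.0 ± 1.04. Mstn, which encodes myostatin, fell from 12.5 ± 2.93 to 1.74 ± 0.149, and its receptor genes Acvr2b and Acvr1b fell by 1.28 and 1.39 on the log2 scale.

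Most cytosolic ribosomal protein genes were higher. Of 75 tested members 68 were higher, or 71 adjusted over the list alone, and 0 lower, with a median log2 fold change of 0.80. Rpl3 rose from 3.17 ± 0.435 to 27.2 ± 5.06, Rpl13 from 14.7 ± 5.30 to 81.8 ± 21.8 and Rpl10a from 4.0 ± 0.527 to 23.9 ± 4.23. Reads of these genes can be shared with pseudogenes. The camera adjusted p was 2.75e-17, and the adjusted p was 0.264 with an estimated correlation.

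More inflammation genes and macrophage markers were higher than lower. Lgals3, a macrophage lectin, rose from 1.28 ± 0.451 to 19.5 ± 1.42, Tlr4, the endotoxin receptor, from 1.28 ± 0.50 to 14.7 ± 2.09, and Ccl8, a chemokine, from 0.194 ± 0.265 to 4.11 ± 0.333. The chemokine Cxcl12 had a log2 fold change of -0.58, and the interferon-response gene Ifit3 had -0.43, a call that was lost with totals without the 20 most abundant genes (adjusted p = 0.0596). Of 25 inflammation genes 17 were higher and 3 lower, or 4 lower adjusted over the list alone (camera adjusted p = 0.00022, and adjusted p = 0.218 with an estimated correlation). Of 10 macrophage and monocyte markers 8 were higher, with Lyz2, lysozyme, at 9.12 ± 1.51 and 18.7 ± 1.41 and Ccr2, a receptor of monocytes, at 0.226 ± 0.0405 and 1.31 ± 0.240 (camera adjusted p = 0.00161, and adjusted p = 0.218 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, was listed at 0 in all 3 controls and at 10.7, 18.6 and 15.8 in the denervated mice. The neutrophil and mast cell list had 1 higher and 1 lower of 5 and a median of -0.20 against a mean of 0.62 (adjusted p = 0.837), and that median was positive (0.13) under equal protein-coding totals. None of 13 lymphocyte markers in the table reached the level filter.

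Most vessel markers were lower as deposited. Of 12 endothelial markers 10 were lower, with Kdr and Flt1, receptors of vascular growth factor, falling from 6.79 ± 0.494 to 2.35 ± 0.236 and from 12.7 ± 0.889 to 5.11 ± 0.801. Vwf was higher, at 5.94 ± 0.316 and 8.07 ± 0.876, a call lost without control 1 and denervated 2 together (adjusted p = 0.0557). Of 10 pericyte and smooth muscle markers 8 were lower, or 9 adjusted over the list alone, among them Rgs5 from 75.6 ± 2.83 to 25.6 ± 2.91. Des, which fibres also express, was higher. The camera adjusted p was 0.000614 and 0.00182, and the adjusted p for both was 0.218 with an estimated correlation. Both medians, -0.74 and -0.53, turned slightly positive (0.02 and 0.11) under equal protein-coding totals, while staying below the median of all genes. Fibro-adipogenic progenitor markers had 7 of 13 lower, or 8 adjusted over the list alone (adjusted p = 0.0576, with 0.0397 without control 3 and 0.0355 without denervated 1), and tendon markers 5 lower and 1 higher of 8 (adjusted p = 0.23). These medians of -0.34 and -0.49 also turned positive under equal protein-coding totals. Scx, a transcription factor of tendon cells, rose from 0.561 ± 0.214 to 9.11 ± 2.14.

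Matrix genes went both ways. Col1a1 and Col1a2, the chains of type I collagen, fell from 127 ± 23.6 to 44.5 ± 9.82 and from 130 ± 18.8 to 45.4 ± 6.14. Timp1, an inhibitor of matrix proteases, rose from 0.191 ± 0.0783 to 19.3 ± 8.89, and Lox, which cross-links collagen, from 2.75 ± 0.484 to 11.6 ± 2.58. The 32 matrix genes held 10 higher and 14 lower, or 15 lower adjusted over the list alone. Their median was -0.11 and their mean 0.02, the list test did not pass (adjusted p = 0.464), and the median turned positive under totals without the 20 most abundant genes and under equal protein-coding totals.

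Among Schwann cell markers Pmp22, a protein of peripheral myelin, fell from 7.19 ± 0.763 to 2.35 ± 0.371, and Prx, which stabilises myelin, from 1.09 ± 0.238 to 0.198 ± 0.00436. Gldn, a protein of the node of Ranvier, rose from 0.174 ± 0.0263 to 1.65 ± 0.0882. Of 8 myelin markers 5 were lower and 1 higher (adjusted p = 0.0645, and 0.0411 without control 3), with a median of -0.40 that was 0.02 under equal protein-coding totals. Taken less the median of all genes, it was -0.39 as deposited and -0.58 with those totals. Gdnf, a neurotrophic factor, rose from 0.136 ± 0.0715 to 2.36 ± 0.140, and the neurotrophin receptor gene Ngfr from 0.434 ± 0.141 to 1.48 ± 0.190. Of 4 tested repair markers 3 were higher and 0 lower (camera adjusted p = 0.0281, and adjusted p = 0.218 with an estimated correlation), and the call was lost with totals that left out the 20 most abundant genes (adjusted p = 0.0634).

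Satellite cell markers were divided, with Sdc4 and Cdh15 higher and Chodl and Heyl lower among 6 (adjusted p = 0.433). The call of Heyl was lost without control 1, control 2, denervated 1 or denervated 2 (adjusted p = 0.0968, 0.0914, 0.0909 and 0.0968). Adipocyte markers had 5 higher and 2 lower of 7 (adjusted p = 0.223). Car3, a carbonic anhydrase that muscle also expresses, went from 514 ± 34.9 to 2875 ± 211, and Plin4, a lipid droplet protein, fell from 40.1 ± 8.17 to 11.9 ± 0.983. Spindle and myotendinous markers had 2 higher of 6, Ankrd1 and Egr3, with a median of -0.09 against a mean of 0.92 (adjusted p = 0.457), and the median was positive under totals without the 20 most abundant genes and under equal protein-coding totals. Of 6 erythrocyte markers 0 were higher and 2 lower, Bpgm and Alas2 (adjusted p = 0.251). Alas2 missed the threshold without control 1, control 3, denervated 1 or denervated 3 (adjusted p = 0.0811, 0.0516, 0.0597 and 0.0744). The list median of -0.27 was 0.2 without control 1 and 0.034 without control 2, and without control 3 the list passed (adjusted p = 0.00689, median -1.26). It was positive under totals without the 20 most abundant genes and under equal protein-coding totals. Cell division genes were near the floor, with 5 of 20 tested and only Rrm2 called, from 0.111 ± 0.0527 to 0.957 ± 0.378 (list adjusted p = 0.441).

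Stress and clock genes moved in part. Gpx3, an extracellular glutathione peroxidase, rose from 23.4 ± 3.99 to 107 ± 29.3 and Hspb1, a small heat shock protein, from 69.2 ± 7.96 to 150 ± 21.6. Sod2, the mitochondrial superoxide dismutase, fell from 42.5 ± 1.74 to 15.5 ± 0.281, and Chac1, which degrades glutathione, from 31.9 ± 8.71 to 5.02 ± 0.843. Of 29 stress genes 12 were higher and 3 lower (adjusted p = 0.0561, with 0.0268 without control 1 and 0.0304 without denervated 3). Bmal1, listed as Arntl, and Clock, the activators of the circadian loop, rose from 0.708 ± 0.0546 to 2.05 ± 0.366 and from 2.44 ± 0.0820 to 5.01 ± 0.514. Bhlhe41, a repressor of the loop, fell from 8.78 ± 0.707 to 2.46 ± 0.640, whereas Nr1d1, also a repressor, had a log2 fold change of 0.46 (adjusted p = 0.0351), a call lost without control 1, control 3, denervated 1 or denervated 3 (adjusted p = 0.0959, 0.0877, 0.111 and 0.108). Of 17 clock genes 5 were higher and 6 lower, or 8 lower adjusted over the list alone (adjusted p = 0.464), and the median of -0.15 turned positive under totals without the 20 most abundant genes and under equal protein-coding totals. The time of day of tissue collection is not given in the sources used here.

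The largest changes outside the lists were of several kinds. Cpne2, a calcium-dependent membrane-binding protein, rose from 1.4 ± 0.303 to 152 ± 14.6, Aif1l from 0.839 ± 0.579 to 109 ± 10.6 and Krt18, an epithelial keratin, from 0.0220 ± 0.0215 to 58.9 ± 12.2. Rrad, a small GTPase that restrains calcium channels, rose from 0.552 ± 0.353 to 82.2 ± 4.33, and Hamp2, a relative of the liver hormone hepcidin, from 2.40 ± 0.864 to 134 ± 15.5. The nucleolar RNA Snora26 was listed at 0 in all 3 controls and at 71.5, 158 and 70.7 in the denervated mice. Dhrs7c, a reductase of the sarcoplasmic reticulum, fell from 59.1 ± 8.48 to 1.45 ± 0.220, Mlf1 from 49.9 ± 5.95 to 1.77 ± 0.309 and Mylk2, the skeletal muscle myosin light chain kinase, from 175 ± 8.50 to 15.3 ± 1.98. The uncharacterised genes A530098C11Rik and 2310065F04Rik fell by 3.76 and 3.4 on the log2 scale. Gm12319, annotated as antisense, and Gm10800, a member of a family of near-identical rows, fell by 3.59 and 3.79, and both are uncertain for those reasons. Among the most abundant rows SNORA48 (ENSMUSG00000084708) rose from 11750 ± 2937 to 40436 ± 5806. The 7SK row ENSMUSG00000065037 had a log2 fold change of 0.50, a call that was lost without control 1, control 2 or denervated 1 (adjusted p = 0.0555, 0.0681 and 0.0556).

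**Figure D3:**
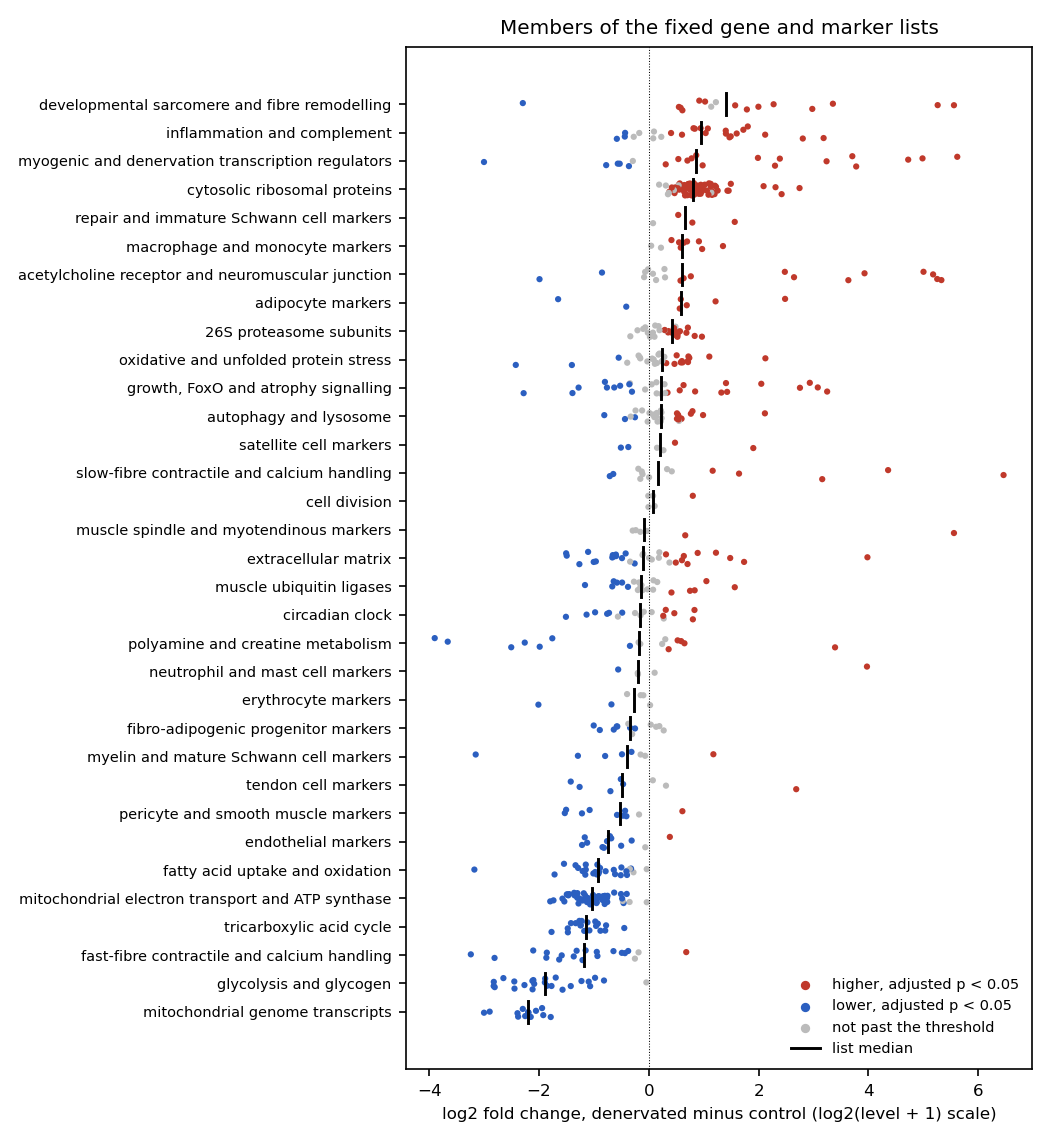
Log2 fold change, denervated minus control on the log2(level + 1) scale (horizontal axis), of each tested member of the 33 lists, with values as deposited. Points are genes, red for higher, blue for lower and grey for not past the threshold, and black bars are list medians, from -2.2 for the mitochondrial genome to 1.4 for developmental genes. Equal protein-coding totals would move the median of all genes from -0.01 to 0.60 and turn the medians of ubiquitin ligases, polyamine, matrix and clock genes and of progenitor, neutrophil, endothelial, pericyte, myelin, tendon, erythrocyte and spindle markers positive. Taken less the median of all genes, only the polyamine median would turn.

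By camera with the preset correlation 9 lists were higher and 8 lower, and with an estimated correlation 0 lists passed in either direction. Lists with an estimate near or below the preset 0.01 lost their calls too: endothelial (-0.0014), repair Schwann (-0.054) and developmental genes (0.012). The other called lists had higher estimates, up to 0.62 for the mitochondrial genome. A correlation above the preset is therefore not the whole cause of the lost calls. Missing the threshold with an estimated correlation does not show that a list was unmoved. The preset test also called 9 to 19 lists when the same 6 libraries were split in other ways. Each of those splits mixed control and denervated libraries on both sides, so part of the group difference stayed in them. They do not show how often the list test calls without a difference. Counts of members share the libraries and scaling of the list tests and are to be read against the 47.3% of all tested genes that were called. Under equal protein-coding totals 16 of 82 named genes called lower had the other sign, the largest fall among them being -0.85 for Scn4a. Among the others were Atf4, Trim54, Fbxo31 (ENSMUSG00000052934), Tfeb, Bnip3, Lamp1, Casq2, Mybpc1, Cxcl12, Prdx3, Heyl, Cd34, Fmod and Lipe. Control 1 and denervated 2 stood apart from their groups in Lars2 (735 and 766, against 74.1 to 378 in the other libraries) and in Gm15662 (12871 and 10435, against 1810 to 6006), rows chosen after their values were seen. Leaving out both gave 2378 higher and 2509 lower genes.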

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

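TPM without the library factor, leaving out control 1 and denervated 2 together, 1 row per set of identical rows and equal protein-coding totals were chosen after the data had been seen, and the other alternatives were planned. Of 157 named genes 140 kept their sign and side of the threshold wherever both were read. Of 33 lists 2 kept the sign of their median and their side, with both other list tests included. Neither was read under a minimum log2 fold change of 1 or with 1 row per set of identical rows. That minimum would end the call of any named gene with a smaller change, such as Trim63 (0.75) or Clock (0.80). A mean level of 1 or more left 148 named genes and not all lists to read. Under equal protein-coding totals only signs were read, and they turned for 16 of 82 named genes called lower and for the medians of 12 lists. Taken less the median of all genes, only the median of the polyamine list turned. Settings for counts and the authors' own fold changes were not run, since the table used here holds neither. Totals without the 20 most abundant genes gave 4966 genes higher and 1614 lower, equal protein-coding totals 9038 and 668, and a minimum log2 fold change of 1 left 758 and 673, against 2840 and 3017. Equal protein-coding totals raise the denervated libraries by construction, since their protein-coding share was 18.1% against 31.7%, so a kept sign of a higher gene shows nothing there. Leaving out 1 library gave 2390 to 2556 higher and 2456 to 2742 lower genes, with 9 to 10 lists higher and 8 to 11 lower. With the replicate block 2636 genes were higher and 2772 lower, the lists stood at 9 and 8, and of the named genes Lamp1, Nr1d1 and Heyl lost their calls. Replicates are separate mice, so the shared numbers give no pairing by design. Deviations from group means correlated by -0.0068, -0.099 and 0.019 for numbers 1 to 3, and not every control library correlated best with its own number. With so few mice this check cannot exclude a factor shared by mice of the same number. Lamp1 reversed to 0.0931 with totals without the 20 most abundant genes (adjusted p = 0.351, range 0.0581 to 0.351 over the settings that ended its call). Signs of results not called turned with the same totals for the AC099934.1 and AC157822.1 pair (0.269, and 0.00699 with TPM without the library factor) and for the medians of ubiquitin ligases (0.141), polyamines (0.139), matrix (0.121), the clock (0.132), erythrocytes (0.0137) and spindles (0.0731), and with no filter for neutrophils (0.105). A call was lost in at least 1 setting for, among others, 7SK (ENSMUSG00000065037), Alas2, Azin1, Bnip3, Cd68, Heyl, Hlf, Ifit3, Lamp1, Lipe, Nr1d1, Odc1, Prdx3 and Vwf. Depth is unknown, so which low genes it limited cannot be said.

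Camera with an estimated correlation called 0 lists higher and 0 lower, with 1 and 4 at an unadjusted p below 0.05, where the preset correlation called 9 and 8 and fry 16 and 11. The calls lost were those of lists with medians of 0.60 for the neuromuscular junction, 0.86 for myogenic regulators, 0.42 for the proteasome, 0.22 for autophagy, -1.18 for fast fibres, 1.4 for developmental genes, -1.89 for glycolysis, -1.04 for nuclear respiratory genes, -2.20 for the mitochondrial genome, -1.15 for the tricarboxylic acid cycle, -0.93 for fatty acids, 0.94 for inflammation, 0.80 for ribosomal proteins, 0.61 for macrophages, -0.74 for endothelium, -0.53 for pericytes and 0.66 for repair Schwann cells. Fry, which does not compare a list with other genes, added growth signalling (0.23), slow fibres (0.17), polyamines (-0.17), stress (0.24), satellite cells (0.21), progenitors (-0.34), myelin (-0.40) and adipocytes (0.58) by the sign of these medians, and neutrophils and spindles as higher, with means of 0.62 and 0.92 against medians of -0.20 and -0.094. The stress list also passed with quantile normalization (0.23), no filter (0.21), a mean of 1 or more (0.24), a pseudocount of 0.01 (0.30) and without control 1 and denervated 2 together (0.21), and its median ran from 0.15 to 0.29 with 1 library left out. Progenitor markers passed with no filter (-0.34) and ran from -0.35 to -0.30. Myelin markers passed with no filter (-0.48), a mean of 1 or more (-0.80), totals without the 20 most abundant genes (-0.24) and TPM without the library factor (-0.36), and ran from -0.42 to -0.39. Erythrocyte markers ran from -1.26 to 0.20. Repair Schwann markers lost their call with totals without the 20 most abundant genes (0.84). A larger correlation is not the whole cause of the lost camera calls. Endothelium (-0.0014) and repair Schwann cells (-0.054) had estimated correlations below the preset 0.01 and lost theirs too. The cause of these differences was otherwise not tested, and a lost call does not show that a list was unmoved.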

Other observations

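The tests of Hist genes against histone variants, of transcript length and of other splits were set before their results were seen, the median of the Hist genes alone being known by then, and the other tests of this part were chosen after. The genes and gene families of this part were chosen after their values were seen. Rpl3l, a ribosomal protein gene of skeletal muscle and heart, fell from 46.3 ± 4.16 to 10.5 ± 1.82 and Rpl3, which can share reads with pseudogenes, rose from 3.17 ± 0.435 to 27.2 ± 5.06, log2 fold changes of -2.05 and 2.74 (limma adjusted p = 1.52e-05 and 6.3e-06, all 3 mice of each group apart). The imprinted non-coding RNA H19 rose from 224 ± 29.4 to 2196 ± 295. Its neighbour Igf2 stood at 2.48 ± 0.414 and 3.29 ± 0.940 (adjusted p = 0.197). Krt8, the partner of Krt18 in keratin filaments, rose from 0.0363 ± 0.0179 to 27.9 ± 6.19, and Eda2r, a receptor of the tumour necrosis factor family, from 1.98 ± 0.0468 to 47.0 ± 4.0.

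Among 117 families of genes with a shared name stem, camera called 8 past an adjusted p of 0.05 with the preset correlation, and the adjusted p was 0.994 for each with an estimated correlation. Of 45 tested Hist genes 35 were higher and 0 lower, with a median log2 fold change of 1.00. Asb genes, substrate adaptors of ubiquitin ligases, had 11 of 16 lower and 1 higher (median -1.10). The Asb median stayed below 0 under the 5 other scalings, at -0.24 with equal protein-coding totals. Mitochondrial ribosomal protein genes of the Mrpl stem had 18 of 47 lower and 4 higher (median -0.24), the opposite balance to the cytosolic set, and that median was positive with totals without the 20 most abundant genes (0.07) and with equal protein-coding totals (0.55), though below the median of all genes in both.

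Small nuclear and nucleolar RNAs were higher in denervated muscle, 51 of 95 rows with identical rows counted a single time and 0 lower, with a median log2 fold change of 1.27. The authors' library factors do not account for it, since their log2 ratio of denervated over control means was -0.087. An equal rise of every RNA without a poly(A) tail is excluded as the whole cause, since 25 small nuclear and nucleolar rows with a mean of 100 or more in both groups differed among themselves by far more than their SE allow (Cochran's Q was 23.4 times its degrees of freedom, and 33.1 times among the 7 of at least 200 nucleotides). Snord17 and SCARNA6, for example, had log2 fold changes of 1.10 (SE 0.133) and -0.21 (SE 0.095). More carry-over of some classes of such RNA stays open. Hist genes, mostly without a tail, lay 0.73 above 6 polyadenylated histone variants by median, a gap past the size set beforehand for this cause. The variants went both ways, however, and a permutation test gave p = 0.0247 for medians and p = 0.127 for mean ranks. A shift in fragment length stays open too, since shorter small RNA rows rose more (Spearman rho -0.41 across rows, which are not independent, permutation p = 1e-05, the smallest the resamples can give). This result met the outcome set beforehand for that cause. Only 68.6% of the 172 rows had a length and entered the test, so it does not decide the question. An effect of denervation on these RNAs was not tested and cannot be told apart from these technical causes.

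Ttr, the liver and choroid plexus carrier of thyroid hormone, was listed at 0 in 3 controls and at 15.6, 15.5 and 14 after denervation, and the hepcidin relative Hamp2 rose to 134. RNA from liver is excluded as the source, because albumin mRNA, the most abundant transcript of hepatocytes, reached at most 0.088 in any denervated library. Among the other hepatocyte transcripts read, Serpina1a averaged 0.595 in controls and 0.499 after denervation, and Trf, transferrin, which other tissues also express, 2.77 and 5.70. Expression in the muscle itself may explain both genes, a hypothesis with no test of its own here.

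Transcripts of the mitochondrial genome fell further than the nuclear genes of the same complexes. A common dilution of fibre transcripts would lower both alike, but the gap between their medians, -1.16 on the log2 scale, is the pattern itself and no separate test, so the part of dilution in either fall stays open. Lower capture of short poly(A) tails could also produce this gap. The mRNA without a tail, mt-Nd6, differed from the median of the other 12 by 0.034, but reads of its opposite strand cannot be separated without a stated strand, so loss and lower capture cannot be told apart by this test. A real loss of mitochondrial transcripts with denervation stays open.

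With 3 mice against 3 there are 10 splits of the libraries, too few for a share below 0.05. The real split gave 2840 higher and 3017 lower genes, and the highest count in 1 direction in any other split was 2, so 1 of 10 splits was as large for each. For the list tests the real split called 17 lists and the highest other split 19, so 2 of 10 were as large. That other split set control 1, control 2 and denervated 3 against the rest. Every split other than the real one mixed control and denervated libraries on both sides. The group difference then adds to the spread within each side, which lowers gene counts, and part of it can still move lists. These counts therefore do not measure what libraries without a group difference would give.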
